A study of Mus musculus with 53 samples.

How the data were processed

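RNA was sequenced from mouse neurons, astrocytes and brain tissue. Per the labels' protocols, RNA was extracted with Trizol, cleaned on RNeasy Micro columns, made into TruSeq libraries and sequenced on an Illumina HiSeq instrument. The labels give 53 samples in 19 groups. The embryonic cortex group was read from the source name in the labels, neuron and hippocampus groups from the treatment and astrocyte groups from the sample titles. The values used here are 1 column of RPKM that the authors deposited for the embryonic cortex as a mean, to which the labels assign 3 libraries, so that it was used as the authors' mean with no SD. Labels of several groups share replicate numbers, but no column for a single library was used, so nothing was paired. Whether the 3 libraries came from separate animals is not given in the sources used here.

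Per the submitters' processing notes, the tools named for the series were Bowtie2 2.1.0, TopHat2 2.0.9, Cuffdiff 2.0.2, HTSeq 0.6.0 and DESeq 1.16.0, on the mouse build mm9 (NCBIM37), with no role given to any of them. Which of them made the deposited RPKM values is not given in the sources used here, nor is the read length, strand or treatment of reads that map to several places. An exact 0 can be a gene with no read or one whose reads could not be assigned, so such genes are said to be listed at 0.

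Symbols and lengths came from GENCODE M21, which is made on a later build than the authors' own, so no coordinates are given. Of all gene IDs, 32919 had a symbol and a length, and the 5072 others held 2.30% of the summed RPKM. Gene span is the distance from the first to the last base of the gene with its introns, and exon length is the union of all its exons. To find which length the authors had used, each low value of a multi-exon gene was multiplied by each length. The 3 fullest narrow peaks with span were taken as the worth of 1 read in 1 library. Values within 0.5% of these peaks were counted for both lengths, and exon length was given no peaks of its own. Span was taken as the length, since most values lay on these peaks with it. The peaks gave library totals of 51.3, 64.8 and 71.6 M reads, with no way to tell which library is which. In single-exon genes of up to 1 kb, 628 of 678 values (92.6%) lay on a peak with the length taken as end minus start, and 303 of 679 (44.6%) with both ends counted. Reads of a gene that lies inside another gene on the same strand were not all counted for the outer gene in the 5 cases with an inner gene of at least 10 RPM and an outer gene of stable length: the outer gene was below the inner one in 5, as in Agbl4 at 1.10 against Bend5 at 23.7 RPM, named here after their values were seen. Whether other reads within introns were counted was not tested. Reads per gene were estimated as RPKM times span times the summed depth. Intervals and floors from them cover counting error only.

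The gene lists, differences between lists, gene pairs, families and the rule for named genes were fixed before the data were examined. Each list's statistic was the median of log2(RPKM + 0.1) over its members listed above 0. Its percentile was taken among 10000 random lists of the same size drawn from all genes above 0, and a list was called in the upper or lower 2.5%. Differences were the first list's median minus the second's, set against random pairs of lists in the same way, without genes in both. On the log2(RPKM + 0.1) scale differences of low genes are understated. Genes are not replicates, so a percentile describes these libraries and is not a p-value. The text names the 10 highest genes, all members of the H3.3, HIRA and ATRX, DAXX and DEK lists, both genes of each of 18 pairs, and of each other list the 3 highest and the lowest detected member, or all where 6 or fewer were measured. Some genes and pairs that the rule names are not reported here. Genes named beyond this rule are said to be so. Members that could not be matched by name were Hist1h3d, Hist1h3f, Hist1h3g, Hist1h3h and Hist1h3i of the replication-coupled H3 genes, H1f0 of the other histone variants, Pou3f2 of the upper-layer genes and Ahsp of the red blood cell genes. Near-identical genes, such as the replication-coupled histones, globins, tubulins and mitochondrial genes with nuclear copies, are uncertain where reads could not be assigned to 1 of them, as are overlapping genes such as Xist and Tsix.

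The alternatives fixed beforehand were pseudocounts of 1 and 0.01, a background of all listed genes or of genes at 1 RPKM or more, with the members of each list taken by the same limit, the mean in place of the median, lists without their highest member, random lists matched on span in 10 bins, other detection thresholds, a rescaled sum, repeated names collapsed, and sums without mitochondrial and ribosomal genes. Leaving out single replicates was not possible with 1 column. Chosen after seeing the data were 5 more: values per kilobase of exon for every gene with a length, the same for the 18508 genes of stable length, a background of protein-coding genes, and that background with each of the rescaled values. Sums of reads with no length were added for the shares of the highest genes and of families. A length was called stable where the span in GENCODE M21 lay within 5% of that in RefSeq (GRCm38.p6), or the gene was mitochondrially encoded. Genes whose symbol had no match in RefSeq were thereby not called stable either, and were not told apart from genes whose spans differ. Among low values, 364 of 401 (90.8%) with agreeing spans lay on a peak, and 141 of 179 (78.8%) with differing ones, so some rescaled values rest on lengths other than the authors'. A list turned direction in an alternative when it crossed the middle of the random lists, whether or not it was called.

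The steps were tested on simulated data. In 3 simulated libraries of 70, 60 and 50 M reads, 18464 multi-exon genes were above 0. Peaks were sought for each length by itself, whereas in the data they were sought with span only. The length that had been used was found both for span and for exon length, and with span the depths were recovered. The search with span only was thus not tested on values divided by exon length, nor was another number of libraries than 3. For the list test, of 400 simulated lists of 15 genes drawn at random from 24426 genes, 3% were called high and 1.75% low. Of 400 drawn from the top 10% of genes, 100% were called high, and of 400 from the lower 20%, 100% were called low. Computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9.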

Results

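The series measured messenger RNA by sequencing in 53 mouse libraries of 19 groups. They came from cultured cortical neurons left at rest or depolarised with potassium chloride, neurons and astrocytes carrying a control miR construct or one for the histone genes H3f3a and H3f3b, with or without added H3.1 or H3.3, hippocampus of adults in normal or enriched housing, and cortex of untreated embryos (E16.5). Neuron groups held 2 to 4 libraries, and all other groups 3. The stated aim was to test how neuronal activity and adult plasticity act through histone turnover on mRNA levels. The values used here are those of the embryonic cortex alone, 3 libraries given as 1 authors' mean per gene in RPKM, reads per kilobase of gene scaled to the library's total. The other 50 libraries of 18 groups are not analysed here, so no group is compared with another. Because only a mean was given, no value below has an SD, and no p-value is given. The number of libraries, 3, was taken from the labels. With it, the low values gave libraries of 51.3, 64.8 and 71.6 M reads, together 188 M reads. A gene with no read in them could still have had up to 3 reads, which is 0.0160 RPM (reads scaled to the library's total in M reads), or 0.00160 RPKM for a gene of 10 kb.

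The deposited values count each gene's reads per kilobase of the whole gene, introns included, so genes with long introns have low values for their reads. Among low values of multi-exon genes, 660 of 744 (88.7%) fell within 0.5% of a value that 1 read in 1 of the 3 libraries would give when multiplied by the whole-gene span. With exon length instead, 34 of 575 (5.91%) did so, where an even spread would give 5.62%. Levels of different genes are therefore compared below as deposited. For gene pairs a ratio per kilobase of exon is added where it differs by more than 1.5 times. Values per kilobase of exon take all counted reads to lie in exons. Beyond genes nested in others, whether reads within introns were counted was not tested. Orders that turn on that scale rest on this. Gene lists were compared with random lists: the percentile is that of the list's median among 10000 random lists of as many genes listed above 0, and a list is called high or low in the upper or lower 2.5%.

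**Figure D1:**
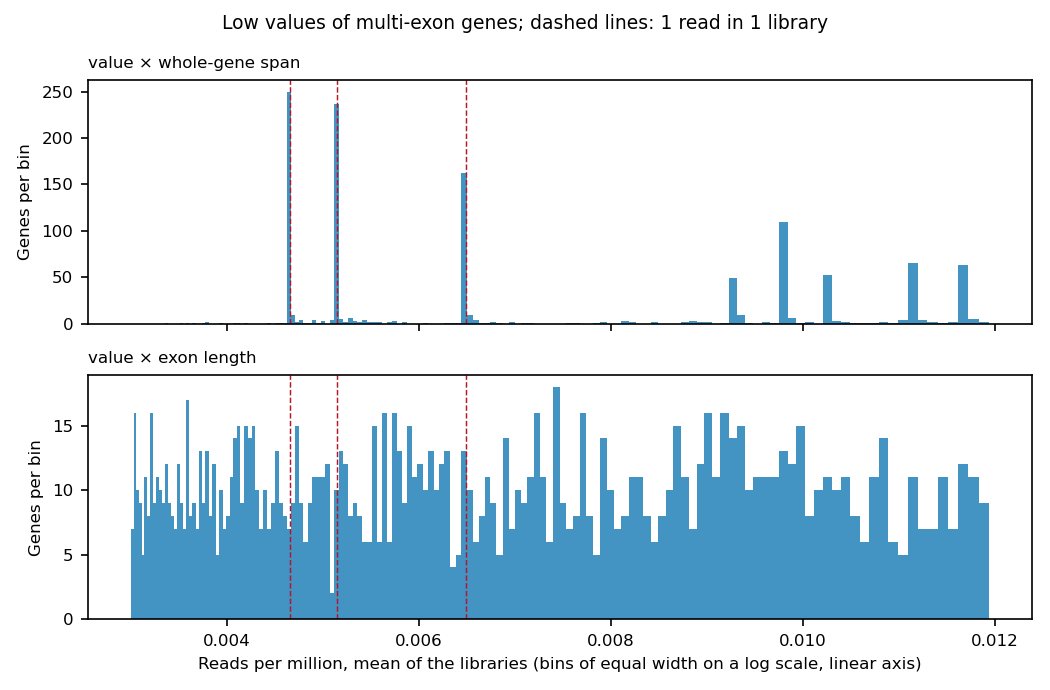
Histograms of low values of multi-exon genes after multiplication by the whole-gene span (upper panel) or by the exon length (lower panel), as RPM on the x axis and genes per bin on the y axis. In the upper panel the genes pile up on the dashed lines at 0.00466, 0.00514 and 0.00650 RPM, the worth of 1 read in each library, and in the lower panel they do not.

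Mitochondrial transcripts and tubulins were among the highest in the embryonic cortex by deposited RPKM. The 10 highest genes held 24.5% of the summed RPKM, while the 10 highest per kilobase of exon held 11.3% of that sum and the 10 highest by reads with no length 5.85% of the reads. The 10 by RPKM were the cytochrome oxidase genes mt-Co3 (3694 RPKM), mt-Co1 (3556) and mt-Co2 (3334), cytochrome b (mt-Cytb, 2533), the alpha-tubulin Tuba1a (1346), the short predicted microRNA gene Gm23935 (1309), mt-Nd1 (1242), mt-Nd4 (1179), the beta-tubulin Tubb2b (852) and mt-Nd2 (697). Without mitochondrially encoded genes, the 10 highest held 10.8%. Of all gene IDs listed, 7129 reached 1 RPKM, 1001 reached 10 RPKM and 85 reached 100 RPKM, while 13565 (35.7%) were listed at 0. Of 20214 protein-coding genes, 6385 reached 1 RPKM. By exon length, 11671 of the genes with a length did so.

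H3.3, the histone H3 variant put into chromatin outside DNA replication, had measured transcript levels far above those of the replication-coupled H3 genes. Whether the libraries yielded fewer reads from histone transcripts without a poly(A) tail was tested on histone genes as a group and stayed open. H3f3b (ENSMUSG00000016559) stood at 117 RPKM and H3f3a (ENSMUSG00000060743) at 16.6 RPKM, a median of 44.1 RPKM for the pair of genes, at percentile 99.9. H3f3b was 7.06-fold above H3f3a as deposited. The ratio by exon length was 3.83, with lengths not called stable for either gene. The 7 measured replication-coupled H3 genes were all under 1 RPKM: Hist2h3c2 at 0.418, Hist1h3c at 0.253, Hist1h3a at 0.182 and Hist1h3b at 0.0600, with Hist2h3b and Hist2h3c1, named after their values were seen, listed at 0. Their detected members had a median of 0.182 RPKM (percentile 49.0, and 79.2 against all listed genes), and 5 of the 12 genes of that list could not be matched by name. The median of the H3.3 genes exceeded theirs by 7.29 on the log2(RPKM + 0.1) scale, at percentile 99.9 of random differences. Every setting able to give this call kept it. The difference was 8.75 per kilobase of exon with any gene length, 6.05 without the highest member of each list and 5.27 with a pseudocount of 1. These H3 genes are near-identical in sequence, so their values are uncertain where reads could not be assigned to 1 copy.

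Other histone variants were abundant too. All 10 measured members reached 1 RPKM, with a median of 12.5 RPKM (percentile 100). Hist3h2ba stood at 86.9, H2afz, the H2A.Z gene, at 60.4, H2afx, whose product is phosphorylated at DNA breaks, at 36.0 and the macroH2A gene H2afy, the lowest, at 2.69 RPKM. With exon lengths called stable 1 member remained, and the list was not called. Whether the others differed in length or had no match by symbol in RefSeq was not told apart.

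The chaperones that place H3.3 were present at moderate levels. Of the HIRA complex and its partner, Asf1a stood at 2.39 RPKM, Ubn1 at 1.99, Ubn2 at 1.28, Hira itself at 1.25 and Cabin1 at 0.787 RPKM, a median of 1.28 (percentile 88.9, not called), which turned to percentile 7.10 when genes under 1 RPKM were left out. Daxx stood at 6.39, Dek at 4.11 and Atrx at 3.22 RPKM, a median of 4.11 (percentile 97.2, just short of a call). The difference between these lists, -1.61 on the log2 scale, lay at percentile 24.3, and was -0.88 per kilobase of exon with stable lengths. Hira was 0.195 times Daxx and 0.387 times Atrx as deposited. Per kilobase of exon the order with Daxx turned, 18.7 for Hira against 12.5 for Daxx, and Hira and Atrx (19.5) came within 1.5 times of each other. An estimated 21832 reads lay behind the value of Hira and 7408 behind that of Daxx, so counting error alone is small for both.

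The replication-linked H3 chaperones were not called. Their 7 genes had a median of 0.659 RPKM (percentile 78.9), from Nasp, which holds soluble H3, at 7.90, Rbbp4 at 7.79 and Mcm2 at 2.66 down to Cdan1 at 0.214 RPKM. The HIRA list exceeded them by 0.86 on the log2 scale (percentile 66.7, not called), a difference that turned to -2.22 when genes under 1 RPKM were left out. Asf1a was 7.85-fold above its paralog Asf1b (0.304 RPKM), and 4.28-fold per kilobase of exon. The other histone chaperones were high as a list: all 11 passed 1 RPKM, with nucleophosmin Npm1 at 33.1, Set at 20.8, the FACT subunit Ssrp1 at 20.2 and the other FACT subunit Supt16, the lowest, at 2.77 RPKM, and a median of 8.65 (percentile 100).

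**Figure D2:**
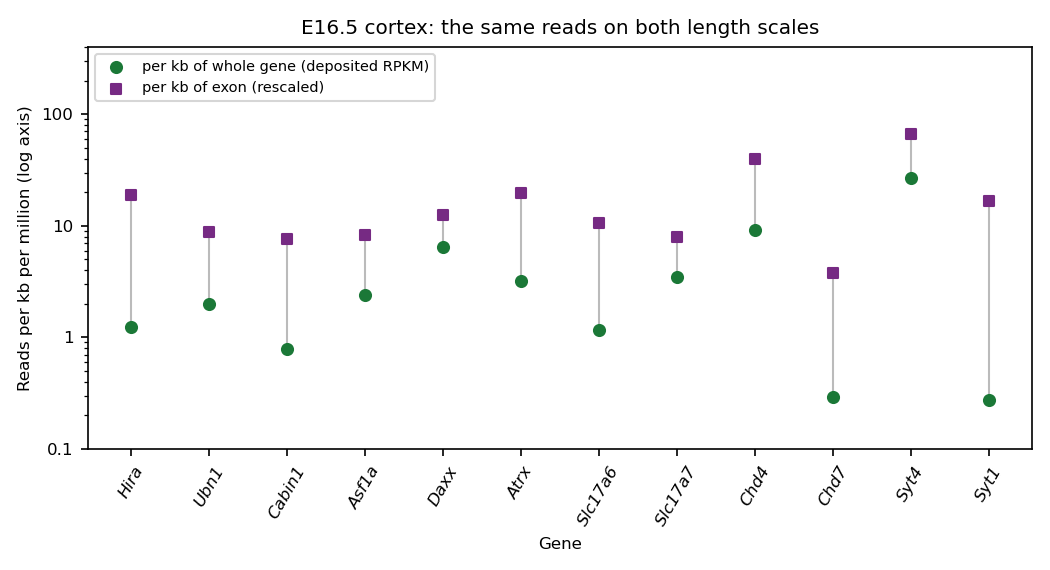
Each gene's level in the cortex mean as deposited, per kilobase of whole gene (green circles), and with the same reads per kilobase of exon (purple squares), on a log axis of RPM per kilobase. Hira lies below Daxx as deposited (1.25 against 6.39) and above it per kilobase of exon (18.7 against 12.5), and Slc17a6 and Slc17a7 trade places likewise. The exon scale takes all counted reads to lie in exons, which was not tested.

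Chromatin remodellers and Polycomb genes stood high as a list, with 14 of 21 at 1 RPKM or more and a median of 1.85 RPKM (percentile 99.9). Among them were the deacetylase gene Hdac2 at 10.3, the NuRD helicase gene Chd4 at 9.19, the demethylase gene Kdm6b at 8.40 and the DNA methyltransferase gene Dnmt3b, the lowest, at 0.114 RPKM. With genes under 1 RPKM left out the list lay at percentile 72.6. Chd4 was 31.4-fold above Chd7 (0.292) as deposited and 10.6-fold per kilobase of exon. Ezh2 (2.04), a Polycomb methyltransferase gene, was 2.16-fold above Ezh1 (0.945), and 4.44-fold per kilobase of exon. Dnmt3a (0.939) was 8.26-fold above Dnmt3b, and Smarca4 (5.19) was 3.71-fold above Smarca2 (1.40). Actl6b, the neuronal subunit of the BAF complex, stood at 7.35 RPKM and the progenitor subunit Actl6a at 1.85 RPKM, so Actl6a was 0.252 times Actl6b.

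The cortical lineage was represented from progenitor to neuron. All 13 radial glia genes passed 1 RPKM, with Fabp7 at 102, Vim at 31.0, Sox2 at 20.2 and Notch1, the lowest, at 1.09 RPKM, and a median of 3.52 (percentile 99.98). Their call was lost at percentile 70.7 when genes under 1 RPKM were left out. For intermediate progenitors, Neurog2 stood at 29.7, Insm1 at 27.8, Eomes at 15.4 and Neurog1 at 0.537 RPKM, with a list median of 8.98 (percentile 100, 7 of 9 at 1 RPKM). New and migrating neurons had the highest median of the lineage lists, 19.8 RPKM (percentile 100, 12 of 14 at 1 RPKM), led by Tubb2b (852), Stmn1 (223) and Neurod6 (194), with Unc5d at 0.167 RPKM. They exceeded radial glia by 2.46 on the log2 scale, at percentile 96.7 and thus not called. That difference was called with a pseudocount of 1 (2.21), against all listed genes (2.46) and with genes under 1 RPKM left out (3.78). It was also called with means (2.01) and with random lists matched on span (2.46). No other setting called it, including values per kilobase of exon with any gene length (3.37, percentile 94.3). Percentiles there ran from 88.2 with stable exon lengths to 97.39 with any exon length against protein-coding genes. Radial glia minus intermediate progenitors was -1.33 (percentile 19.7), and 0.21 per kilobase of exon with stable gene lengths.

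Genes of the cortical layers ranged widely within each list. Of the deep-layer genes, Fezf2 stood at 27.0, Tbr1 at 24.4, Wnt7b at 3.20 and Foxp2 at 0.0455 RPKM, with a median of 1.74 (percentile 98.4, 6 of 11 at 1 RPKM). Without Fezf2 that list lay at percentile 95.8, against protein-coding genes at 94.6 and with genes under 1 RPKM left out at 41.4, none of them called. Of the upper-layer genes, Pou3f3 stood at 86.0, Lhx2 at 5.98, Mef2c at 2.25 and Rorb at 0.163 RPKM, with Pou3f1, named after its value was seen, listed at 0 and a median of 0.773 (percentile 89.0, 4 of 11 at 1 RPKM). Upper-layer genes were called high per kilobase of exon (percentile 99.8 with stable gene lengths). Deep-layer minus upper-layer genes was 1.08 on the log2 scale (percentile 76.7, not called), was 0.02 per kilobase of exon with stable lengths, and turned to -0.06 with means and to -0.44 when genes under 1 RPKM were left out. Subplate genes had a median of 0.230 RPKM (percentile 53.4), with Nr4a2 at 2.57, Nxph4 at 1.12, Ccn2 at 0.879 and Moxd1 at 0.0168 RPKM. Cajal-Retzius genes had a median of 0.367 RPKM (percentile 68.1), with the reelin gene Reln at 0.786, Ndnf at 0.563, Lhx5 at 0.439 and Ebf2 at 0.00653 RPKM. None of the 9 reached 1 RPKM, although an estimated 67876 reads lay behind Reln, a gene with a long span. Per kilobase of exon with stable lengths the subplate list turned to percentile 39.7 and the Cajal-Retzius list to 47.6.

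Cortical interneuron genes were high as a list with the deposited values. Sst stood at 20.1, Dlx1 at 17.8, the receptor gene Cxcr4 at 7.53 and Erbb4, a very long gene, at 0.0661 RPKM, with a median of 2.27 (percentile 99.8, 10 of 15 at 1 RPKM). The call was lost with genes under 1 RPKM left out (percentile 68.6), per kilobase of exon with any gene length (97.49) and, against protein-coding genes, per kilobase of exon with stable (95.7) or any length (88.9). Genes of the striatum and ganglionic eminences, where these neurons arise, had a median of 0.148 RPKM (percentile 38.9, and 86.9 against all listed genes), with Olig2 at 2.81, Ppp1r1b at 2.41 and Rarb at 0.00425 RPKM. The difference, 3.26 on the log2 scale, lay at percentile 99.5 and was called. It was 0.40 at percentile 70.1 when genes under 1 RPKM were left out. Thalamic and hindbrain genes were called low, with a median of 0.0121 RPKM over detected members (percentile 1.29) and 5 of 15 listed at 0. The vesicular glutamate transporter gene Slc17a6 reached 1.15 RPKM, while Irx3 stood at 0.0626, Lef1 at 0.0275 and Pax5 at 5.44e-05 RPKM. That call was lost against all listed genes (percentile 32.1), with genes under 1 RPKM left out (6.58, with Slc17a6 the 1 member left) and per kilobase of exon with stable lengths (3.66).

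Markers of cells outside the neuronal lineage ranged widely, from members listed at 0 to the adult globin genes of red blood cells. None of these lists was called high with the deposited values against genes above 0. Astrocyte genes had a median of 0.627 RPKM (percentile 85.5, and 98.6 against all listed genes, a call), with Aldoc at 17.4, Apoe at 7.11, Sox9, which radial glia share, at 3.97 and Gjb6 at 0.00185 RPKM. Radial glia exceeded astrocyte genes by 2.73 on the log2 scale, called at percentile 97.51 and lost with a pseudocount of 0.01 (percentile 92.1), with exon lengths and with a protein-coding background. It turned to -0.50 when genes under 1 RPKM were left out. Oligodendrocyte precursor genes had a median of 0.380 RPKM (percentile 68.7, and 40.4 per kilobase of exon with stable lengths), with Olig1 at 6.50, Olig2 at 2.81, Gpr17 at 0.934 and Bmp4 at 0.00566 RPKM. Myelin genes had a median of 0.0242 RPKM (percentile 6.85), with Mog at 1.02, Cnp at 0.387 and Mobp at 0.000205 RPKM, and were not called. They lay at percentile 52.6 against all listed genes and at 0.77, a low call, with genes under 1 RPKM left out. Mog, just above that limit, was the 1 member left, so the limit itself brings that call.

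Microglia and macrophage genes had a median of 0.208 RPKM (percentile 52.1), led by the complement genes C1qc (1.03), C1qa (0.942) and C1qb (0.581), with Ptprc at 0.00689 RPKM. With genes under 1 RPKM left out, 1 member remained, C1qc, at percentile 1.34 and so called low. A gene just above that limit must lie low among genes that all pass it. Per kilobase of exon with stable lengths the list lay at 38.2. Endothelial genes had a median of 0.280 RPKM (percentile 62.5, and 45.03 per kilobase of exon with stable lengths), with the tight-junction gene Cldn5 at 17.3, Mfsd2a at 1.57, Slc2a1 at 1.39 and Slco1a4 at 0.000726 RPKM, and exceeded microglial genes by 0.30 on the log2 scale (percentile 58.9). Pericyte genes had a median of 0.365 RPKM (percentile 69.7, and 42.2 against protein-coding genes), with Vtn at 2.60, Rgs5 at 1.41, Kcnj8 at 0.944 and Acta2 at 0.0130 RPKM. Meningeal and fibroblast genes had a median of 0.0662 RPKM (percentile 18.9, and 79.1 against all listed genes), with Igf2 at 1.55, Islr at 0.567, Foxc1 at 0.436 and Aldh1a2 at 0.000804 RPKM. Red blood cell genes were split: the adult globin genes Hba-a1, Hbb-bs and Hba-a2 stood at 53.6, 52.6 and 48.3 RPKM, while the embryonic globin gene Hbb-bh1 stood at 0.00425 RPKM and the list median was 0.226 (percentile 54.7). With genes under 1 RPKM left out, 4 of its 11 members remained, and these were called high at percentile 100. The list turned to 39.9 without its highest member, 28.1 against protein-coding genes and 11.2 per kilobase of exon with stable lengths. Choroid plexus and ependymal genes were called low, with a median of 0.0163 RPKM (percentile 2.35). Foxj1 stood at 0.803, the transthyretin gene Ttr at 0.0670, Aqp1 at 0.0490 and Kl at 0.00104 RPKM. The call was lost when random lists were matched on gene span (percentile 3.04), against all listed genes (42.05) and per kilobase of exon (4.32 with stable lengths).

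Cell-cycle genes were high as a list, with 19 of 24 at 1 RPKM or more and a median of 2.11 RPKM (percentile 99.99). The replication clamp gene Pcna stood at 24.5, Mcm7 at 14.8, the ribonucleotide reductase gene Rrm2 at 9.56 and the cyclin gene Ccne1 at 0.534 RPKM. With genes under 1 RPKM left out the list lay at percentile 47.7. Activity-regulated genes were not called in this untreated tissue, except against all listed genes, where immediate early genes lay at percentile 99.5 and late ones at 97.8. Per kilobase of exon with stable lengths they turned to the low side, at percentiles 21.4 and 14.5, and against protein-coding genes as well to 10.99 and 6.78. Immediate early genes had a median of 0.503 RPKM (percentile 86.3, 8 of 20 at 1 RPKM), with Ier5 at 24.2, Jun at 11.1, Dusp1 at 8.88 and Fosb at 0.0181 RPKM. Late activity-regulated genes had a median of 0.396 RPKM (percentile 76.5, 6 of 17 at 1 RPKM), with the neuropeptide gene Sst at 20.1, Nrn1 at 5.17, Rgs2 at 3.07 and Cartpt at 0.0157 RPKM. Immediate early minus late genes was 0.28 on the log2 scale (percentile 58.1), and -0.30 per kilobase of exon with any gene length.

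Presynaptic genes were high as a list, and the excitatory and inhibitory synapse lists were not called. The excitatory list mostly holds receptor and scaffold genes, with the vesicular transporter genes Slc17a6 and Slc17a7 of the presynaptic side among them. Presynaptic genes had a median of 2.77 RPKM (percentile 99.98, 14 of 18 at 1 RPKM), with the vesicle genes Vamp2 at 55.9, Rab3a at 36.1 and Syt4 at 26.7 RPKM. They lay at percentile 94.2, not called, with genes under 1 RPKM left out. Excitatory synapse genes had a median of 0.726 RPKM (percentile 94.3, 8 of 20 at 1 RPKM), with the AMPA receptor gene Gria2 at 7.65, Dlg4 at 7.29 and Grin2a at 0.00302 RPKM. Excitatory synapse genes were called high with random lists matched on gene span (percentile 99.02), against all listed genes (99.7) and per kilobase of exon with any length (99.7). Inhibitory synapse genes had a median of 0.290 RPKM (percentile 64.4, and 32.5 against protein-coding genes), with Nlgn2 at 18.6, the chloride cotransporter genes Slc12a2 at 0.801 and Slc12a5 at 0.710, and Gabrb1 at 0.0134 RPKM. Presynaptic minus excitatory synapse genes was 1.80 on the log2 scale (percentile 93.9), and excitatory minus inhibitory 1.08 (percentile 81.2), neither called with these settings, the latter turning to -2.26 when genes under 1 RPKM were left out, with Nlgn2 the 1 inhibitory synapse gene left. The presynaptic difference was called with a pseudocount of 1 (1.13), against all listed genes (1.80) and with means (1.91).

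Paralogs, some of which change over as neurons mature, were compared by their levels, with no test. The NMDA receptor gene Grin2b (0.119 RPKM) was 39.2-fold above Grin2a, and the importer Slc12a2 was 1.13-fold above the exporter Slc12a5. Slc17a6 was 0.330 times Slc17a7 (3.49) as deposited and 1.33-fold above it per kilobase of exon. Camk2b (3.39) was 7.41-fold above Camk2a (0.457). Syt4 was 98.1-fold above Syt1 (0.272) as deposited and 3.93-fold per kilobase of exon. Dlg2 (0.0556) was 0.00763 times Dlg4 as deposited and 0.400 times per kilobase of exon, with a length of Dlg4 that was not called stable. The ubiquitous Cox6a1 (30.1) was 1228-fold above the muscle form Cox6a2 (0.0245), for which about 4 reads were counted, and 4173-fold per kilobase of exon.

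Ribosomal protein genes and mitochondrially encoded genes had the highest medians of the 38 lists. All 21 cytoplasmic ribosomal protein genes passed 1 RPKM, from Rplp1 at 301, Rplp0 at 169 and Rpl7a at 165 down to Rpl18 at 35.9 RPKM, with a median of 80.9 (percentile 100). The mitochondrially encoded genes had a median of 484 RPKM (percentile 100), and all but mt-Nd4l (0.0348) stood at 99.3 RPKM or more. Nuclear genes of the respiratory chain had a median of 10.3 RPKM (percentile 100), with the ATP synthase genes Atp5b at 89.4 and Atp5a1 at 54.0, Cox6a1 at 30.1 and Cox6a2 at 0.0245 RPKM. Genes of liver, muscle, pancreas and testis were called low, with a median of 0.00299 RPKM over detected members (percentile 0.01) and 6 of 20 listed at 0. The highest were Acta1 at 0.298, Apoa1 at 0.101 and Prm1 at 0.0617 RPKM, and the lowest detected was Ins2 at 0.000247 RPKM. Against all listed genes the call was lost (percentile 12.6). The X-inactivation transcript Xist stood at 111 RPKM and its antisense partner Tsix at 0.00158 RPKM, while the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0. The sex of the embryos is not given in the sources used here. That list, with 2 detected members, lay at percentile 94.4. It was called high with a pseudocount of 1 (percentile 98.4) and with genes under 1 RPKM left out (98.9, Xist alone), and turned to 6.01 against all listed genes and to 7.29 without Xist.

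**Figure D3:**
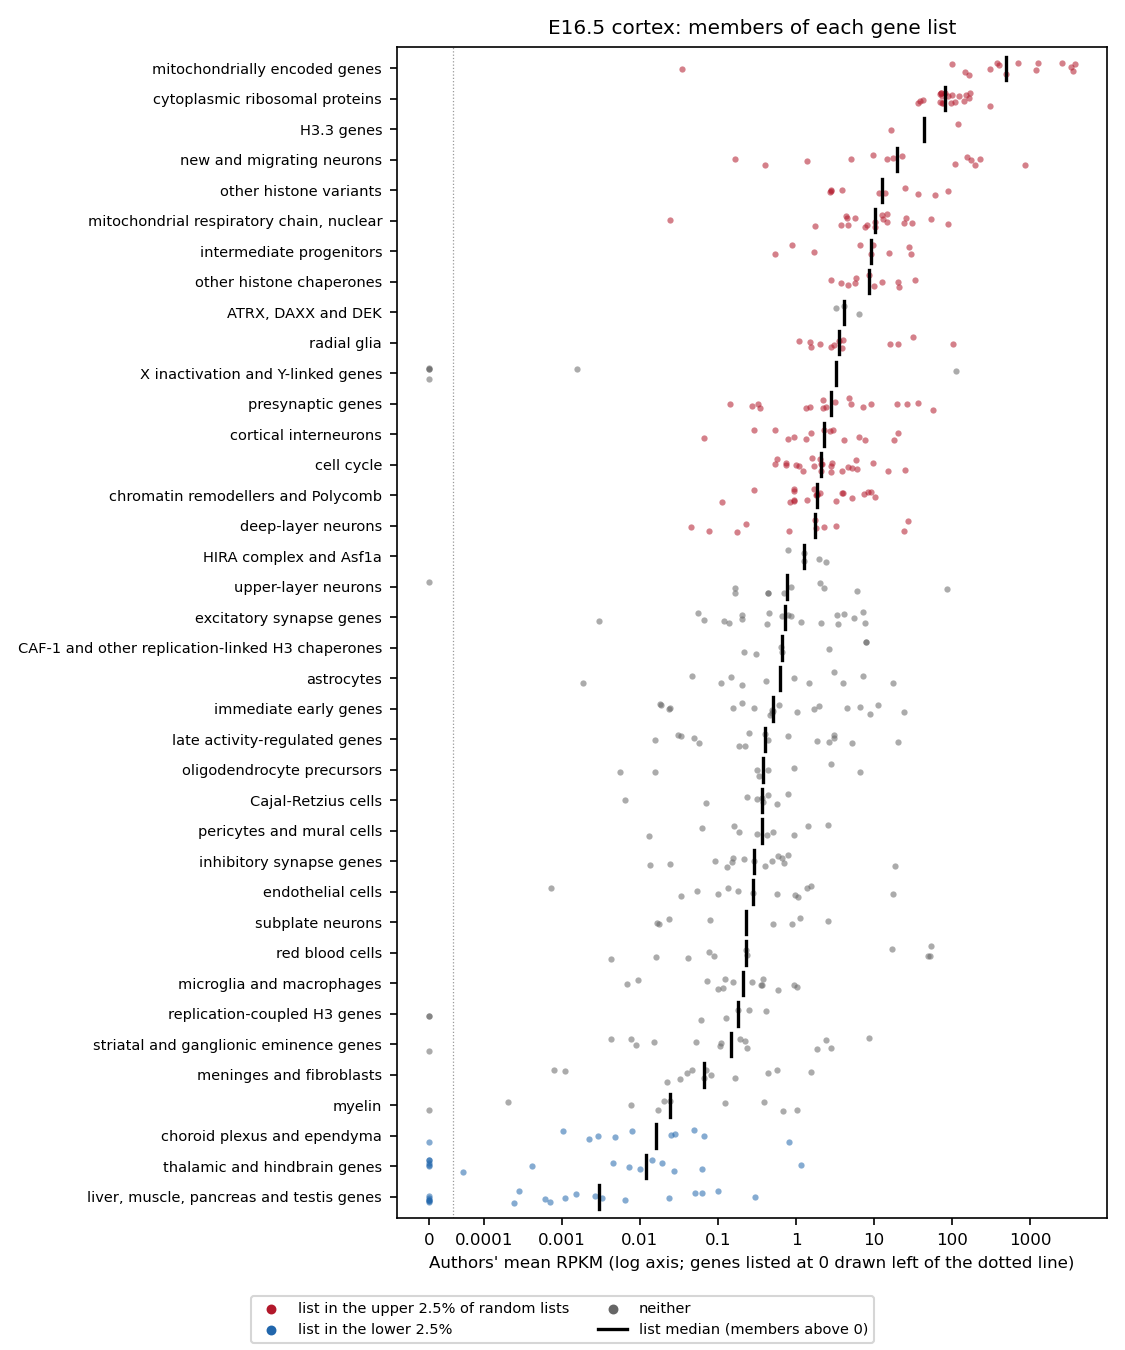
Every measured member of the 38 gene lists as a point at its authors' mean RPKM on a log axis, with genes listed at 0 drawn left of the dotted line and the median of detected members as a black bar. Red lists lie in the upper 2.5% of random lists, blue lists in the lower 2.5% and grey lists in neither. Medians run from 484 RPKM for mitochondrially encoded genes to 0.00299 RPKM for genes of other tissues.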

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

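The 5 settings that use exon length or a protein-coding background, and the sums of reads with no length, were chosen after the data were seen. In what follows the number after a list is its percentile and that after a difference its log2 value, and the cause was not tested unless one is named. Of the 14 high lists, 7 kept their call in every one of the 12 settings that gave them a value: H3.3 genes, intermediate progenitors, new neurons, other histone chaperones, ribosomal proteins, mitochondrially encoded genes and nuclear respiratory genes. With the 7 planned settings 8 did so. None of the 3 low lists kept its call in all of them, and CAF-1 genes alone of 21 other lists stayed uncalled and on their side throughout. The H3.3 genes and the replication-coupled H3 genes have no lengths called stable, which can also mean symbols with no match in RefSeq. With stable lengths 36 of 38 lists and 11 of 12 differences therefore gave a value. With genes under 1 RPKM left out 34 lists and 11 differences did. No paired analysis was possible because the values are 1 mean, although the labels share replicate numbers, and for the same reason leaving out a replicate could not be run.

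With a pseudocount of 1, X and Y genes (98.4) gained a call. New neurons minus radial glia (2.21) and presynaptic genes minus excitatory synapse genes (1.13) gained a call. With a pseudocount of 0.01, radial glia minus astrocytes (2.97) lost the call. Against all listed genes, thalamic and hindbrain genes (32.1), choroid plexus (42.05) and other-tissue genes (12.6) lost the call. ATRX, DAXX and DEK (98.8), upper-layer neurons (97.95), astrocytes (98.6), immediate early genes (99.5), late activity genes (97.8) and excitatory synapse genes (99.7) gained a call. New neurons minus radial glia (2.46) and presynaptic genes minus excitatory synapse genes (1.80) gained a call. Replication-coupled H3 (79.2), striatal genes (86.9), myelin (52.6), meninges (79.1) and X and Y genes (6.01) turned direction. With genes under 1 RPKM left out, remodellers (72.6), radial glia (70.7), cortical interneurons (68.6), thalamic and hindbrain genes (6.58) and presynaptic genes (94.2) lost the call. Cortical interneurons minus striatal genes (0.40) lost the call. Myelin (0.77), red blood cells (100) and X and Y genes (98.9) gained a call, with 1 member left of myelin and of X and Y genes and 4 of red blood cells. New neurons minus radial glia (3.78) gained a call. HIRA genes (7.1), deep-layer neurons (41.4), subplate neurons (12.5), microglia (1.34), endothelial cells (4.14), pericytes (18.7) and cell cycle (47.7) turned direction. Of these, microglia were thereby called low, with 1 member left, and the deep-layer and cell-cycle lists lost their calls. A single member just above 1 RPKM, as C1qc (1.03) of microglia and Mog (1.02) of myelin were, must lie low in that background. HIRA genes minus CAF-1 genes (-2.22), deep-layer neurons minus upper-layer neurons (-0.44), radial glia minus astrocytes (-0.50) and excitatory synapse genes minus inhibitory synapse genes (-2.26, with 1 inhibitory gene left) turned direction, and radial glia minus astrocytes thereby lost its call. With means of log2 values, ATRX, DAXX and DEK (98.6), upper-layer neurons (98.3) and meninges (2.49) gained a call. New neurons minus radial glia (2.01) and presynaptic genes minus excitatory synapse genes (1.91) gained a call. Subplate neurons (38.2), Cajal-Retzius cells (35.7), microglia (18.4) and inhibitory synapse genes (48.97) turned direction. Deep-layer neurons minus upper-layer neurons (-0.0562) turned direction. Without each list's highest member, deep-layer neurons (95.8) lost the call. Subplate neurons (29.9), microglia (43.1), red blood cells (39.9) and X and Y genes (7.29) turned direction. Matched on span, choroid plexus (3.04) lost the call. Upper-layer neurons (98.99) and excitatory synapse genes (99.02) gained a call. New neurons minus radial glia (2.46) gained a call. Replication-coupled H3 (76.7) and microglia (39.3) turned direction. All listed genes include those at 0, both in the random lists and among the members of each list.

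Per kilobase of exon with stable lengths, other histone variants (58.5), thalamic and hindbrain genes (3.66) and choroid plexus (4.32) lost the call. Radial glia minus astrocytes (2.83) lost the call. Upper-layer neurons (99.8) gained a call. Subplate neurons (39.7), Cajal-Retzius cells (47.6), oligodendrocyte precursors (40.4), microglia (38.2), endothelial cells (45.03), red blood cells (11.2), immediate early genes (21.4) and late activity genes (14.5) turned direction. Radial glia minus intermediate progenitors (0.21) turned direction. Per kilobase of exon with any length, cortical interneurons (97.49) and choroid plexus (5.2) lost the call. Radial glia minus astrocytes (1.99) lost the call. ATRX, DAXX and DEK (97.7), upper-layer neurons (99.96) and excitatory synapse genes (99.7) gained a call. Red blood cells (31.97), immediate early genes (42.03) and late activity genes (49.1) turned direction. Immediate early genes minus late activity genes (-0.30) turned direction. Against protein-coding genes, deep-layer neurons (94.6) lost the call. Radial glia minus astrocytes (2.73) lost the call. Subplate neurons (29.4), Cajal-Retzius cells (42.97), oligodendrocyte precursors (46.1), microglia (23.4), endothelial cells (32.9), pericytes (42.2), red blood cells (28.1), late activity genes (44.6) and inhibitory synapse genes (32.5) turned direction. With stable exon lengths and that background together, other histone variants (52.7), cortical interneurons (95.7) and cell cycle (97.2) lost the call. Radial glia minus astrocytes (2.83) lost the call. Upper-layer neurons (99.6), myelin (1.74) and meninges (2.23) gained a call. Subplate neurons (29.2), Cajal-Retzius cells (35.8), oligodendrocyte precursors (29.9), microglia (25.1), endothelial cells (31.2), pericytes (43.6), red blood cells (6.58), immediate early genes (10.99) and late activity genes (6.78) turned direction. Radial glia minus intermediate progenitors (0.21) turned direction. With any exon length and that background, cortical interneurons (88.9) lost the call. Radial glia minus astrocytes (1.99) lost the call. Upper-layer neurons (99.8) and excitatory synapse genes (97.54) gained a call. Subplate neurons (32.6), Cajal-Retzius cells (39.3), oligodendrocyte precursors (24.1), microglia (29.7), endothelial cells (33.5), pericytes (40.6), red blood cells (9.33), immediate early genes (8.24) and late activity genes (13.8) turned direction. Immediate early genes minus late activity genes (-0.30) turned direction. With stable lengths 1 member of the other histone variants was left.

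Some values without a test changed too. Per kilobase of exon with any length, 11671 genes reached 1 RPKM, the 10 highest held 11.3% of the sum, and the log2 ratios of Slc17a6 to Slc17a7 (0.41) and Hira to Daxx (0.58) turned direction. Rescaled to the sum that TPM have, 14562 genes reached 1. The 10 highest held 10.8% without mitochondrially encoded genes, and 5.85% of reads with no length. Their share was 11.97% when genes named Rpl or Rps with a number were left out beside the mitochondrially encoded ones. Depth limits the lowest values, such as Cox6a2 with about 4 reads, and a gene of 10 kb listed at 0 may lie anywhere under 0.00160 RPKM, whereas against all listed genes such zeros alone moved the thalamic and hindbrain list to percentile 32.1.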

Other observations

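The tests of whole-gene span, of long transcripts and of short gene length were chosen after their results were seen. No biological explanation was tested, since the values hold 1 group.

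Most sensory receptor genes were listed at 0 in the embryonic cortex, where 35.7% of all gene IDs were, and a 0 in families of similar copies can also mean reads that were not assigned. Of 985 olfactory receptor genes 907 were listed at 0 and 1 reached 1 RPKM, Olfr613 at 1.69 RPKM. Of 365 vomeronasal receptor genes 331 were at 0. Of the clustered protocadherins, which give neurons individual surface codes, 24 were listed by symbol. None of these was at 0 and 13 reached 1 RPKM, with Pcdhb17 the highest at 4.20 RPKM. Small nucleolar RNA genes reached 1 RPKM in 51 of 112 cases, up to Snord104 at 50.4 RPKM. They held 0.466% of the summed RPKM and 0.00401% of the reads. MicroRNA genes and hosts with a Mir name reached it in 51 of 612, up to Mir5125 at 118 RPKM. These held 0.431% and 0.00922%, and leave out Gm23935, a microRNA gene counted below with the predicted genes. Ribosomal protein genes were taken by name as Rpl or Rps with a number, which leaves out genes such as Rplp0 and Rplp1. Genes so named, pseudogenes and any others included, held 7.79% of the summed RPKM, 6.00% per kilobase of exon and 2.70% of the reads. Mitochondrial genes held 22.8%, 8.86% and 2.23%, and 10030 predicted genes 3.91%, 1.90% and 0.324%, with Gm23935 at 1309 RPKM the highest of these. Keratin-associated protein genes, which belong to hair, were at 0 in 46 of 53 cases and none reached 1 RPKM. The genes named with their levels here were picked as the highest of their family, after their values were seen.

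Among nuclear genes of stable length, the highest per kilobase of exon were Tubb3 (887), Ptma (875), Tubb5 (852), Rplp1 (760) and Nkain2 (759 RPM per kilobase of exon), named here after their values were seen. Nkain2 was listed at 2.97 RPKM as deposited, with a span of 1.20e+06 bases and an exon length of 4710 bases. Its place here may not hold if reads within its introns were counted, which was not tested. Genes without a stable length are not among these, and some stood higher with the lengths used, such as Tuba1a (2886), Eef1a1 (1856) and Tubb2b (1381). All 17 Y-chromosome genes were listed at 0, beside 92.1% of olfactory receptor genes, and the sex of the embryos is not given in the sources used here.

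Deposited RPKM fell with the span of the gene: across 12724 protein-coding genes of stable length Spearman's rho was -0.26, with genes not independent replicates. The tables argue against long transcripts as the reason, since rho with exon length was positive (0.104). A candidate explanation is the division of the reads by the whole-gene span. With the same reads per kilobase of exon, rho with span was 0.0343. On that scale Hira lay above Daxx, and upper-layer genes lay with the high lists. Differences in level between genes with and without long introns may therefore be a property of the unit.

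Histone genes with a Hist name, most of them replication-coupled, lay far below cell-cycle genes. The 54 that are protein-coding had a median of 0.124 RPKM, 17.1-fold under the cell-cycle list, and 6 reached 1 RPKM, among them Hist3h2ba and Hist3h2a, the latter named after its value was seen, which also belong to the list of other histone variants. Division by span is argued against, because it hardly lowers genes without introns: the span of these genes over their exon length had a median of 0.998 and was under 1.1 in 49 of the 54. Reads shared between near-identical copies may add to the gap but stay open. The 7 histone genes with at least 90% of their 50-base words in no other gene's transcripts had a median of 0.153 RPKM. That median lay 13.8-fold under the cell-cycle list, and the median of the other 47 genes was 0.110 RPKM. The median of at least 1 RPKM set beforehand for this cause was thus not reached. To argue against sharing, 10 such genes had been asked for, and the 7 ranged from 0 to 5.94 RPKM. A low yield of transcripts without a poly(A) tail could also lie behind the gap and stays open too. The 20 genes with an annotated 3′ UTR over 200 bases had a median 2.74 times that of the 26 with a shorter one. This ratio lay between the bounds of 4 and 1.5 set beforehand.

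The mitochondrial gene mt-Nd4l stood at 0.0348 RPKM, about 2 reads, where the other 12 mitochondrial protein-coding genes stood at 99.3 RPKM or more. Short length is argued against by mt-Atp8, named after its value was seen, which is shorter and stood at 99.3 RPKM. Reads shared with transcripts of other annotated genes met the condition set beforehand, as 1.21% of the 50-base words of mt-Nd4l were found in no other annotated gene. That condition was too weak, because 4 other mitochondrial genes shared as much (at most 2.01% of words of their own) and stood between 400.5 and 3694 RPKM, so sharing alone does not account for it. No explanation tested here remained, and the authors' own annotation of the gene was not used here.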
